A study of Homo sapiens with 12 samples.

How the data were processed

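Total RNA of ME-1 cells isolated alive on a Ficoll gradient was sequenced on a DNBseq instrument. The labels give 2 sets used here. In set 1 cells were transduced in triplicate with lentivirus for MYH11 or scramble shRNA, kept in puromycin at 5 µg/mL from day 3 to day 6, and collected on day 7. Set 3 compared NRP1 shRNA with scramble by a similar procedure. All 12 libraries, 3 in each of 4 groups, were used, and 0 columns of values were left unused. The columns of the MYH11 set carry an abbreviation in place of a gene name and were matched to their samples by elimination.

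The deposited values are TPM, which the authors computed for each library. Per the submitters' processing notes, featureCounts 1.5.2 and DESeq2 were named, with the builds hg38 and GRCh38.p12. The aligner and the gene annotation are not given in the sources used here. The table lists 17281 entries, and 23 gene names that occur more than once (58 entries, with values crossed as when tables are joined on the name) were left out, which gave 17223 genes. The names are symbols, and identifiers and coordinates were taken from GENCODE 29 on GRCh38.

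Whole read counts were recovered from the TPM values by a search for the library factor that makes length times TPM whole within 0.001 read. With GENCODE 29 lengths 99.99% of genes in set 1 and 48.07% in set 3 were whole in every library. For 8942 genes in set 3 another length was needed, after which 99.99% were whole. The recovered depth was 19424110 to 21975918 reads per library. Recovered reads serve for depth, for counting error and for 1 alternative, and the fits use TPM.

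Values were log2-transformed after adding 1 TPM, and genes with a mean of at least 1 TPM in a group compared were tested. Each knockdown was compared with the scramble libraries of its set in limma 3.58.1 (R 4.3.3; lmFit, then eBayes with a trend), two-sided, and p-values were adjusted by Benjamini and Hochberg over all genes tested. The difference between knockdown effects was a contrast in a fit of all 12 libraries. A call is an adjusted p below 0.05. Overlap of calls was tested with Fisher's exact test and the mitochondrial share with an exact permutation test. Recovered reads of megakaryocyte genes were compared by exact binomial tests given the depths.

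For groups of genes, 33 lists of pathways, processes and blood cell markers were written before the data were examined, as were the comparisons, the alternatives (other than leaving out mitochondrial genes, voom, and leaving a target out of its lists, which were added later), and the rule for named genes. Lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01 (30 lists for the MYH11 knockdown and 32 for the NRP1 knockdown), again with an estimated correlation, and with fry. The list of replication-dependent histone genes had 0 tested members, and the erythroid and late granulocyte lists had too few for the MYH11 knockdown.

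The genes named were chosen by rule. They were MYH11, CBFB, NRP1, VEGFA, FLT1, KDR, MYC, MKI67 and PCNA, and per knockdown the 8 largest called rises and falls with groups that do not overlap and a mean of at least 5 TPM in the higher group. To these were added up to 3 called members of each of the 6 lists with the smallest camera p, up to 5 shared genes per direction by their smaller fold change, and 4 differing genes per direction by adjusted p. Unnamed loci and small RNA genes were left out of the largest changes. A gene that the rule names and a list member are not reported here. Further list members are examples picked after their values were seen.

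The calling procedure was tested on simulated data made from these libraries with 50 changed genes per fold. These genes were drawn from those of at least 5 TPM in scramble, so the shares recovered do not cover lower genes such as NRP1. The procedure recovered 18%, 74%, 96% and 98% of genes changed by 1.25, 1.5, 2 and 4-fold at the spread of set 1, where 6.54% of calls were unchanged genes. At the spread of set 3 it recovered 48%, 84%, 100% and 100%, with 2.92% unchanged genes. The simulated changes were few, equally up and down and without a shift of all genes, unlike the data of set 3. The shares of unchanged genes are therefore not those of false calls in the real comparisons. Replicates were checked for duplication by the chi-square per gene between recovered reads of pairs in a group, which was 2.396 to 13.18 and so not that of copies. The first principal component held 61.1% of the variance and separated the sets.

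Alternatives were other pseudocounts and filters, median-of-ratios and quantile scaling, library weights (arrayWeights, whose search stopped early with a warning in 2 fits), no trend, replicate numbers as a block, a joint fit, a minimum fold, leaving out mitochondrial genes, voom on recovered reads, lists without the hairpin's target, and leaving out each library. Reads shared between similar genes (HLA genes, HBD, IGLL1, ribosomal and mitochondrial genes with pseudogene copies) and between overlapping genes were not separated. Figures and tables used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.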

Results

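RNA levels were measured in ME-1 cells, a human acute myeloid leukaemia line that carries inv(16), the inversion that joins the 5' part of CBFB to the 3' part of MYH11. The cells were transduced with lentivirus that expressed a short hairpin RNA (shRNA, which lowers the transcript it pairs with) and were collected on day 7. In set 1 the hairpin against MYH11 was compared with a scramble hairpin, and in set 3 the hairpin against NRP1 was compared with a scramble hairpin. NRP1 encodes neuropilin-1, a co-receptor for VEGF and semaphorins. Each of the 4 groups held 3 libraries, which made 12 in all. The depth recovered from the deposited values was 19424110 to 21975918 reads per library. The values were TPM, the authors' estimate of each transcript's share of its library, for 17223 genes, and fold changes are log2 differences of TPM + 1 between knockdown and scramble, a scale that understates change in genes with low values. A gene or list is called higher or lower where its adjusted p was below 0.05, with limma for genes and its camera test for lists. These p-values measure the spread between libraries of cells transduced in triplicate, which may be largely technical.

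Both hairpins lowered their targets in every library. MYH11 (smooth muscle myosin heavy chain, chromosome 16, 15703172 to 15857033, GRCh38, gene model of GENCODE 29) measured 2.80, 2.30 and 2.54 TPM in the MYH11 shRNA libraries. It measured 8.01, 7.31 and 7.34 TPM in the scramble libraries of that set. The means were 2.55 ± 0.253 and 7.56 ± 0.394 TPM (SD, n = 3 each), from 249 to 321 and 862 to 895 reads per library. MYH11 was therefore 2.97-fold lower (log2 fold change -1.27, SE 0.11, adjusted p 1.79e-05). NRP1 (chromosome 10, 33177492 to 33336262) measured 1.73, 1.65 and 2.04 TPM in the NRP1 shRNA libraries and 4.50, 4.87 and 4.10 TPM in their scramble libraries. Its means were 1.81 ± 0.207 and 4.49 ± 0.388 TPM (SD, n = 3 each), a log2 fold change of -0.97 (SE 0.11, adjusted p 0.000244).

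NRP1 was also lower in the MYH11 knockdown, where its level was 0.574, 0.400 and 0.361 TPM against 2.90, 2.41 and 2.60 TPM in scramble. That 5.93-fold difference had a log2 fold change of -1.33 (SE 0.14, adjusted p 0.000114) and rested on 30 to 47 reads per knockdown library. In the NRP1 knockdown MYH11 measured 7.57, 7.55 and 8.34 TPM against 8.63, 8.59 and 8.49 TPM. Its log2 fold change there of -0.12 was not called (adjusted p 0.214) and was called lower after rescaling by median of ratios (-0.26, adjusted p 0.0105). CBFB, the other partner of the fusion (chromosome 16, 67029116 to 67101058), was not called in the MYH11 knockdown, at 38.4 ± 4.33 against 42.0 ± 4.05 TPM (SD, n = 3 each; limma adjusted p 0.458). With library weights it was called lower (-0.19, adjusted p 0.0191). Exons of MYH11 overlap those of other tested genes, NDE1 among them, on the opposite strand over 6.60% of their length, and gene-level values do not separate the fusion transcript from unrearranged MYH11.

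**Figure D1:**
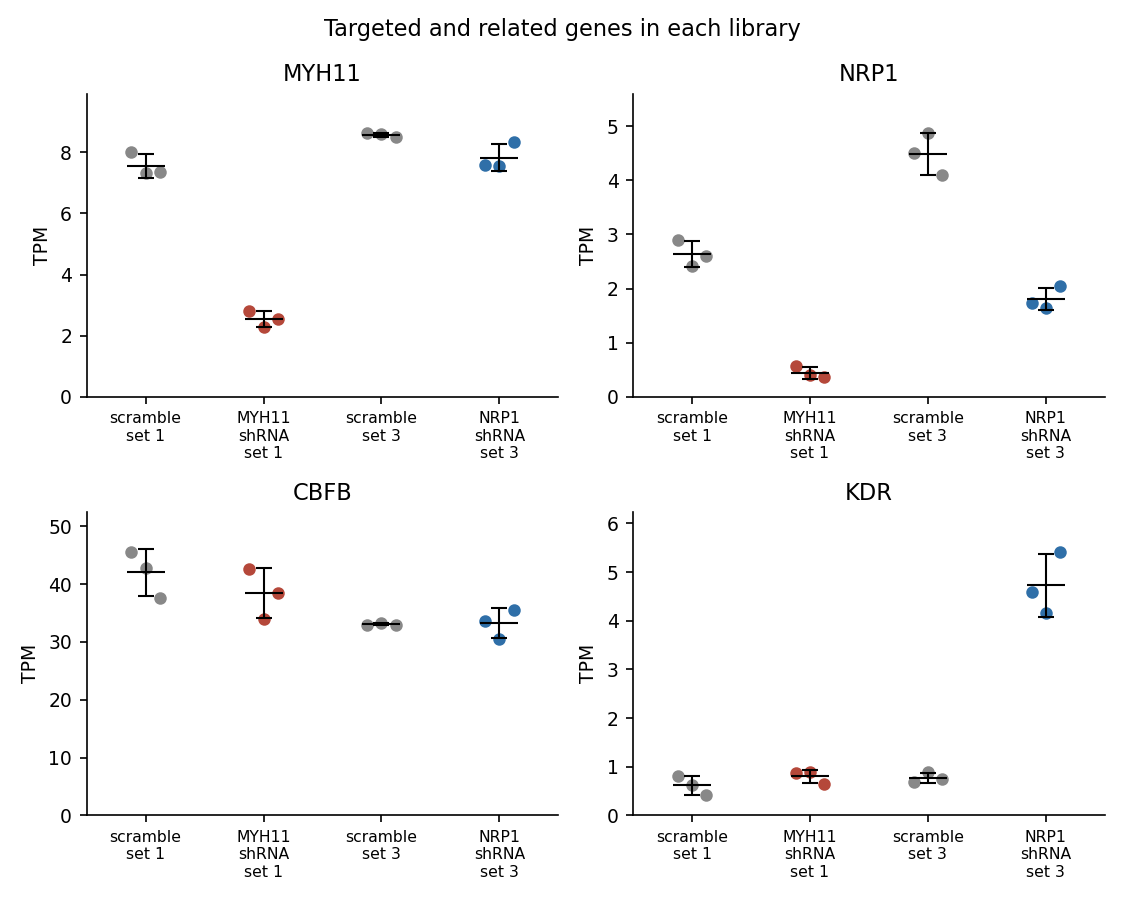
Points show TPM per library and bars the mean with SD (n = 3 per group) for MYH11, NRP1, CBFB and KDR in the 4 groups. NRP1 averaged 0.445 TPM with MYH11 shRNA and 1.81 TPM with NRP1 shRNA, against 2.64 and 4.49 TPM in the respective scramble groups.

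The comparison of MYH11 shRNA with scramble asks which transcripts change when MYH11, whose 3' part lies in the fusion, is targeted. GATA1, the master transcription factor of erythroid and megakaryocyte cells, rose from 18.1 ± 0.974 to 80.2 ± 4.05 TPM (SD, n = 3 each; log2 fold change 2.09, SE 0.08, limma adjusted p 2.59e-07). GATA2, a transcription factor of haematopoietic progenitors and mast cells, rose from 218 ± 6.54 to 730 ± 58.5 TPM (1.74, SE 0.07). The surface glycoprotein CD200 fell from 27.1 ± 3.21 to 3.40 ± 0.197 TPM (-2.67, SE 0.10), and FLT4, the VEGF receptor of lymphatic endothelium, fell from 43.1 ± 2.16 to 8.78 ± 1.06 TPM (-2.18, SE 0.10). All 12 measured genes of MHC class II antigen presentation fell. On GRCh38 GATA1 lies on chromosome X from 48786554 to 48794311 and CD200 on chromosome 3 from 112332347 to 112362812. Of 13097 genes tested, 907 were higher and 1174 lower, among them 118 and 182 by 2-fold or more.

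Other genes with the largest rises were CD38, a surface NAD hydrolase (1.91, SE 0.10, from 4.96 ± 0.524 to 21.3 ± 1.46 TPM), HES1, a target of Notch (1.89, SE 0.17), and SIGLEC10, a sialic acid receptor (1.88, SE 0.09). TRDC, the constant gene of the T cell receptor delta chain, rose by 1.87 (SE 0.19), although 38.8% of its exon length overlaps another tested gene. It had 24 to 35 reads per knockdown library against 2 to 6 in scramble. CNRIP1 rose by 1.87 (SE 0.09) and MYL4, an embryonic myosin light chain, by 1.79 (SE 0.10). Among the largest falls were DYSF, which encodes the membrane repair protein dysferlin (-2.34, SE 0.10), DUSP27 (-2.30, SE 0.12), SHD (-2.25, SE 0.13), TMEM119 (-2.21, SE 0.13) and VPREB1 of the surrogate light chain of pre-B cells (-2.20, SE 0.24). VPREB1 rested on only 0 to 5 reads per knockdown library against 28 to 39 in scramble. NOG, the BMP antagonist noggin, fell from 125 ± 4.37 to 30.2 ± 2.06 TPM (-2.01, SE 0.08). These 16 largest changes were chosen among genes whose groups did not overlap. Over all tested genes, 33.1% had groups that did not overlap, where chance gives 10% for 3 against 3.

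The lists of antigen presentation and of the interferon response were called lower, with members that were not called in all but MHC class II. MHC class II genes, which present peptides to T helper cells, had a median log2 fold change of -0.65, and all 12 also fell when adjusted over the list alone (camera adjusted p 1e-11, and adjusted p = 0.486 with an estimated correlation). HLA-DMA fell by 0.86 on the log2 scale, CD74 by 0.69 and HLA-DRA by 0.63, and their activator CIITA by 0.29. HLA-DRB5 (-0.69) and HLA-DRB1 (-0.67) are near-identical in sequence, so their separate values are uncertain, as are those of other HLA genes. Of 12 genes of MHC class I presentation, 5 fell and 7 were not called, with 5 falling when adjusted over the list alone (adjusted p 0.0036, and adjusted p = 0.604 with an estimated correlation). TAPBP, the tapasin of peptide loading, fell by 0.46 and HLA-C by 0.37 on the log2 scale. Of 22 interferon-stimulated genes, 10 fell, 1 rose and 11 were not called, or 13 and 1 adjusted over the list alone (adjusted p 8.6e-07, and adjusted p = 0.585 with an estimated correlation). The antiviral genes IFITM3 (-1.64, SE 0.07, from 99.7 ± 1.31 to 31.4 ± 1.45 TPM), OAS2 (-1.13, SE 0.12) and BST2 (-0.89, SE 0.07) fell, while CMPK2 rose by 0.33. Of 18 NF-kB and inflammatory genes, 7 fell and 2 rose, or 10 and 3 adjusted over the list alone (adjusted p 0.0036, and adjusted p = 0.585 with an estimated correlation). The chemokine gene CCL5 (-0.84) and TNFAIP2 (-0.79) fell, and CXCL8, the neutrophil attractant, rose (1.22, SE 0.10).

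Genes that mark blood cell stages moved in both directions. Of 22 stem and progenitor genes, 14 fell, 3 rose and 5 were not called, or 14 and 4 adjusted over the list alone (camera adjusted p 3.84e-06, and adjusted p = 0.585 with an estimated correlation). HOPX (-1.90), CRHBP (-1.90), MN1 (-1.77), BAALC (-1.41), PROM1 (-1.40) and the receptor gene FLT3 (-1.06) fell more than CD34 (-0.38), while CD38 (1.91), MEIS1 (0.60) and SOX4 (0.53) rose. Of 15 genes known as marks of inv(16) leukaemia, 8 fell and 3 rose, or 9 and 3 adjusted over the list alone (adjusted p 0.014, and adjusted p = 0.936 with an estimated correlation). MYH11, the hairpin's target, is 1 of the 8, and without it the list was not called (adjusted p 0.0537). SPARC (-1.91), ST18 (-1.69) and CLIP3 (-1.36) fell, against rises of GATA2, CSF2RB (1.36) and IL1RL1 (1.31). Of 7 B cell genes, 5 fell and 1 rose, or 5 and 2 adjusted over the list alone (adjusted p 0.00878, and adjusted p = 0.585 with an estimated correlation), with IGHM at -1.66, DNTT at -0.99 and CD79A at 0.33. Of 9 eosinophil, basophil and mast cell genes, 4 rose and 1 fell, the same counts as adjusted over the list alone (adjusted p 0.00309, and adjusted p = 0.486 with an estimated correlation). HDC, which makes histamine (1.30, SE 0.08), CPA3, the mast cell carboxypeptidase (1.19, SE 0.08), and FCER1A (0.94) rose, while EPX, the eosinophil peroxidase, fell (-0.91). MPO, the peroxidase of primary granules, also fell (-1.62), although its list was not called (adjusted p 0.78).

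Of 10 genes of VEGF and semaphorin signalling, 4 fell, 1 rose and 5 were not called, or 6 and 2 adjusted over the list alone (camera adjusted p 0.0205, and adjusted p = 0.585 with an estimated correlation). FLT4, NRP1, the semaphorin receptor PLXNA1 (-0.76) and GIPC1, an adaptor that binds neuropilin (-0.64), fell, and SEMA3C rose by 0.54. VEGFA itself was not called (0.28, adjusted p 0.0909) and was called higher after rescaling (adjusted p 0.0283). KDR, the main VEGF receptor of endothelium, was below the level tested, at 0.799 ± 0.142 against 0.616 ± 0.189 TPM (SD, n = 3 each). Proliferation genes moved little. Of 30 G2 and M phase genes, 2 rose, HMMR (0.45) and CENPF (0.40), or 1 adjusted over the list alone, and the list was called higher (median 0.13, adjusted p 0.0036, and adjusted p = 0.936 with an estimated correlation). Of 30 G1 and S phase genes, MCM7 rose (0.26) and UHRF1 fell (-0.30), or 0 and 0 adjusted over the list alone. That list was called higher as well (median 0.11, adjusted p 0.0325, and adjusted p = 0.936 with an estimated correlation), and the call was lost without MYH11 shRNA replicate 1 (adjusted p 0.122) and without scramble replicates 2 (0.0858) or 3 (0.0946). After median-of-ratios rescaling more were called, with 7 G2 and M phase genes higher and 0 lower (median 0.14). For G1 and S phase genes it gave 8 higher and 3 lower (median 0.12). MKI67 (0.12, adjusted p 0.516), PCNA (0.09, adjusted p 0.454) and MYC (0.17, adjusted p 0.183) were not called, though MYC was called higher after rescaling (adjusted p 0.0343). Of 26 glycolysis and hypoxia genes, 6 fell and 0 rose, the same adjusted over the list alone (adjusted p 0.0205, and adjusted p = 0.936 with an estimated correlation), among them ADM (-0.89), ENO1 (-0.33) and PKM (-0.30). The glycolysis call was lost without MYH11 shRNA replicate 2 (adjusted p 0.0516) or scramble replicate 1 (0.0748), and the VEGF and inv(16) calls without MYH11 shRNA replicate 1 (0.0533 each).

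The comparison of NRP1 shRNA with scramble asks what changes in these cells when the VEGF co-receptor is lowered. Genes of megakaryocytes, the cells that form platelets, rose: MMRN1, which encodes the platelet protein multimerin, went from 0.719 ± 0.268 to 16.0 ± 0.898 TPM (SD, n = 3 each; log2 fold change 3.32, SE 0.12, limma adjusted p 5.78e-07). ITGB3, the beta chain of the platelet fibrinogen receptor, rose from 1.14 ± 0.0921 to 16.1 ± 1.17 TPM (3.00, SE 0.09), and all 12 measured megakaryocyte genes were higher. CSF1R, the receptor of the macrophage growth factor, rose from 0.757 ± 0.134 to 13.0 ± 0.891 TPM (3.00, SE 0.10). IGLL1 of the pre-B cell surrogate light chain fell from 1868 ± 64.7 to 670.2 ± 12.04 TPM (-1.48, SE 0.04), and 12 of 13 mitochondrially encoded genes fell.

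On GRCh38 MMRN1 lies on chromosome 4 from 89879532 to 89954629 and IGLL1 on chromosome 22 from 23573125 to 23580308. Of 13071 genes tested in set 3, 4519 were higher and 816 lower, so 84.7% of the calls were higher, and 223 rose and 11 fell by 2-fold or more. The median gene was 0.14 higher on the log2 scale. After rescaling the libraries by median of ratios the calls split into 2420 higher and 2254 lower (51.8% higher), and 3236 of the original calls (60.7%) were kept. Quantile normalization gave 2249 higher and 2451 lower. Counts after rescaling are therefore given beside those of the called lists. Mitochondrially encoded genes took 24.6 ± 1.09% of TPM in NRP1 shRNA libraries and 30.5 ± 1.04% in scramble (SD, n = 3 each), a difference of -5.83 percentage points whose two-sided exact permutation p of 0.1 is the smallest that 3 against 3 allow. In set 1 the shares were 29.3 ± 2.91% and 28.1 ± 0.693% (exact permutation p 0.5). Groups did not overlap for 53.2% of genes in set 3, where chance gives 10%.

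**Figure D2:**
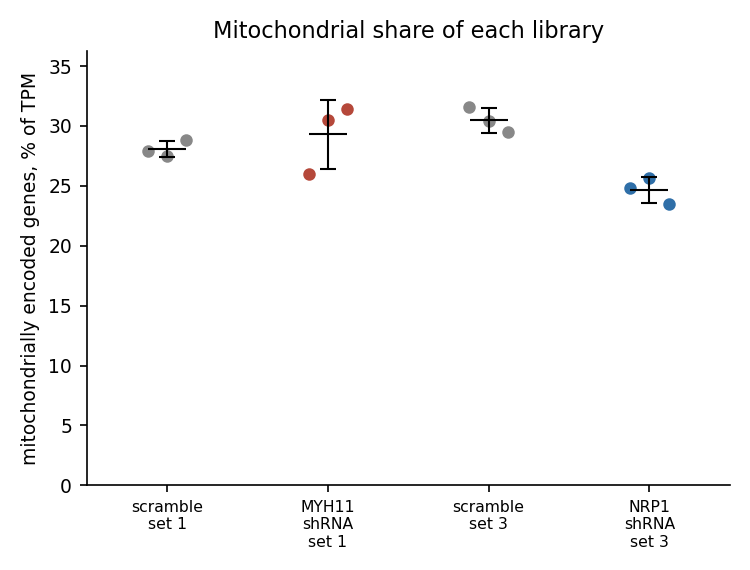
Points show the percentage of TPM taken by mitochondrially encoded genes in each library and bars the mean with SD (n = 3 per group). NRP1 shRNA libraries lay between 23.5% and 25.6%, below the scramble libraries of set 3 at 29.5% to 31.5%, and in set 1 the means were 29.3% and 28.1%.

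Among the 8 largest rises were SELP, the platelet and endothelial adhesion molecule P-selectin (3.19, SE 0.13), TSPAN18 (3.04, SE 0.08), S100A9 of the myeloid protein calprotectin (2.75, SE 0.17), and the inhibitors of differentiation ID3 (3.02, SE 0.09) and ID1 (2.73, SE 0.10). S100A9 had 51 to 62 reads per knockdown library against only 3 to 7 in scramble. ID1 went from 6.14 ± 1.03 to 45.99 ± 0.961 TPM (SD, n = 3 each). The falls were smaller: SERINC2 (-1.41, SE 0.11), AMZ1 (-1.04), RFLNA (-1.04), RNF144A (-1.03), EPX (-0.997, SE 0.06), KDM1B, a histone demethylase (-0.97), and NUDT8 (-0.97). KDR (chromosome 4, 55078259 to 55125595) rose from 0.771 ± 0.102 to 4.72 ± 0.641 TPM (1.69, SE 0.13, limma adjusted p 3e-05). FLT1, another VEGF receptor, was below the level tested, at 0.560 ± 0.113 against 0.105 ± 0.0359 TPM. VEGFA was not called (0.04, adjusted p 0.797). MYC, the growth-promoting transcription factor, fell from 514 ± 0.867 to 442 ± 31.5 TPM (-0.22, adjusted p 0.00877, and -0.38 after median-of-ratios rescaling). MKI67, the proliferation antigen, fell from 53.8 ± 1.93 to 43.5 ± 4.62 TPM (-0.30, adjusted p 0.0105, and -0.46 after rescaling). PCNA (0.03, adjusted p 0.558) and CBFB (0.01, adjusted p 0.952) were not called and were lower after rescaling (-0.12, adjusted p 0.0222 and -0.15, adjusted p 0.0429).

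Blood lineage genes made up several of the groups that changed, in libraries with the lower mitochondrial share given above. Of 12 megakaryocyte genes all 12 rose, also when adjusted over the list alone, with a median of 1.82 (camera adjusted p 2.87e-09, and adjusted p = 0.25 with an estimated correlation). After rescaling 11 rose, with a median of 1.68. GP6, the platelet collagen receptor, rose by 2.34 (SE 0.07), PPBP by 2.61 and TUBB1 by 2.03, and GP9 went from 34.5 ± 2.06 to 114 ± 5.49 TPM (1.69, SE 0.06). Of 8 monocyte genes 5 rose, or 6 adjusted over the list alone, among them S100A8 (1.63) and LYZ, lysozyme (1.02) (median 0.84, adjusted p 0.012, and adjusted p = 0.33 with an estimated correlation). After rescaling 4 monocyte genes rose. The monocyte call was lost without scramble replicate 3 of set 3 (adjusted p 0.0639) and with mitochondrial genes left out (median 0.44, adjusted p 0.0581). Of 11 primary granule genes of neutrophil precursors, 5 fell and 3 rose, as they did adjusted over the list alone (median -0.26, adjusted p 0.00961, and adjusted p = 0.33 with an estimated correlation). CTSG fell by 0.55 on the log2 scale and MPO by 0.26, while SRGN (0.95) and MS4A3 (0.54) rose, and the granule call was lost after rescaling (2 higher and 6 lower, adjusted p 0.162). Of 5 dendritic cell genes FLT3 (-0.75) and CCR7 (-0.65) fell, also adjusted over the list alone, in all 0 higher and 2 lower. That list was called lower and its mean was -0.27, while its median of 0.01 was above 0 (adjusted p 0.0126, and adjusted p = 0.352 with an estimated correlation). After rescaling it had 0 higher and 2 lower, with a median of -0.13.

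**Figure D3:**
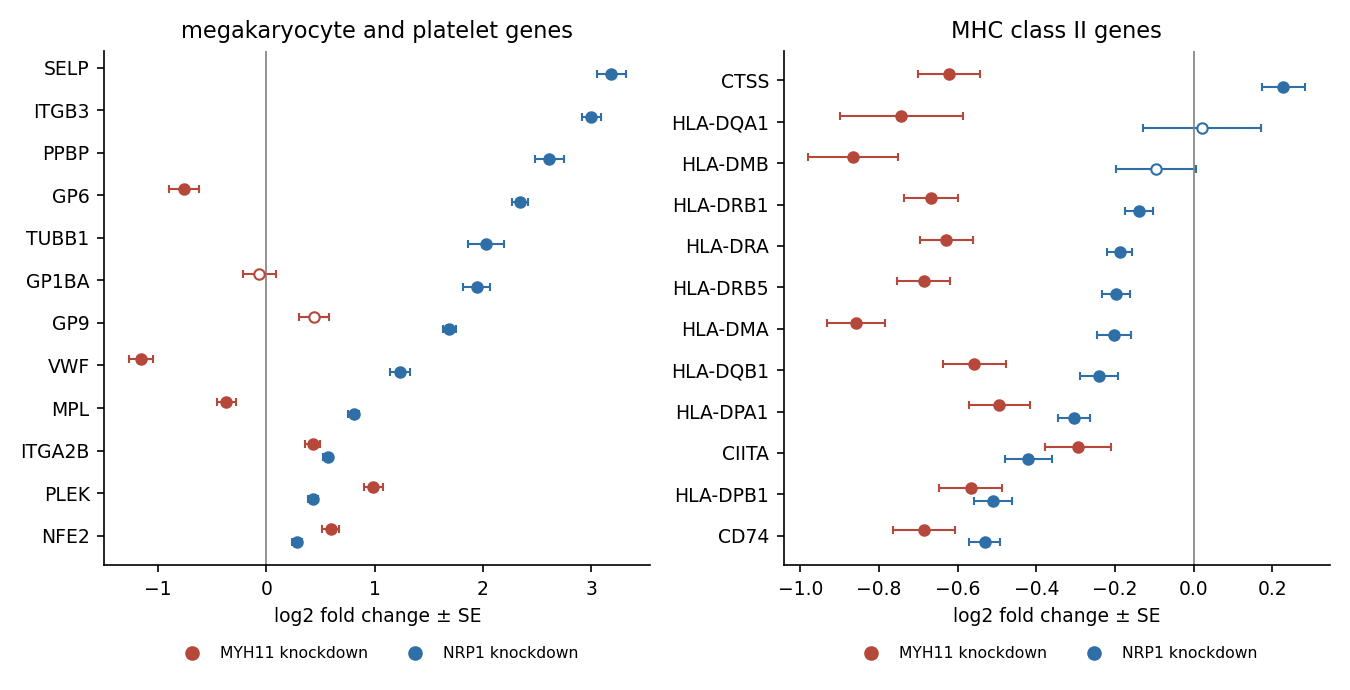
Points show the log2 fold change of TPM + 1 with its SE for each tested megakaryocyte and MHC class II gene in both knockdowns (n = 3 against 3), filled where the gene was called. All 12 megakaryocyte genes rose with NRP1 shRNA, while with MYH11 shRNA 3 of 8 rose and 3 fell, and MHC class II genes fell in 12 of 12 and 9 of 12 cases.

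Of 12 MHC class II genes, 9 fell and 1 rose, as they did adjusted over the list alone (median -0.20, adjusted p 9.7e-09, and adjusted p = 0.25 with an estimated correlation), and the rescaled median was -0.36. CD74 fell from 1139 ± 33.5 to 788 ± 24.3 TPM (SD, n = 3 each; -0.53, SE 0.04), HLA-DPB1 by 0.51 and HLA-DPA1 by 0.30 on the log2 scale, and the protease gene CTSS rose by 0.23 and lost its call after rescaling, with 0 higher and 9 lower. Of 12 MHC class I genes, PSMB9 (-0.37) and PSMB8 (-0.16) fell and B2M (0.45) rose, also adjusted over the list alone, in all 1 higher and 2 lower (median -0.05, adjusted p 0.0278, and adjusted p = 0.352 with an estimated correlation). Rescaling gave 1 higher and 9 lower. The class I call was lost without NRP1 shRNA replicate 1 (adjusted p 0.0503).

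Mitochondrially encoded genes of the respiratory chain had a median of -0.40, and 12 of 13 fell, also adjusted over the list alone (camera adjusted p 1.51e-12, and adjusted p = 0.352 with an estimated correlation). MT-ND4 fell by 0.52, MT-ND5 by 0.46 and MT-CO2 by 0.43 on the log2 scale, and after rescaling 12 fell and 0 rose. Under quantile normalization 2 fell and the list was no longer called (adjusted p 0.242). Nuclear genes of oxidative phosphorylation went the other way, with 23 of 31 higher and 1 lower, or 23 and 2 adjusted over the list alone (adjusted p 0.00961, and adjusted p = 0.605 with an estimated correlation). NDUFA4 rose by 0.61 and COX7A2 by 0.56, but after rescaling 9 were higher and 5 lower and that list was not called (adjusted p 0.233). Of 44 cytosolic ribosomal protein genes, 14 fell and 7 rose, or 14 and 8 adjusted over the list alone (median -0.05, adjusted p 1.42e-05, and adjusted p = 0.605 with an estimated correlation). After rescaling 29 fell and 0 rose, RPL19 (-0.29 before rescaling) and RPL12 (-0.22) among the called genes, and RPL9 (0.24) lost its call (adjusted p 0.244). Under quantile normalization the ribosomal list was not called (adjusted p 0.108).

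The lists of heat shock, glycolysis and p53 target genes were called higher. Of 15 heat shock genes 12 rose and 0 fell, as they did adjusted over the list alone (median 0.29, adjusted p 0.00221, and adjusted p = 0.352 with an estimated correlation), and 7 rose after rescaling. The chaperone genes HSPE1 (0.70, SE 0.06), HSP90AA1 (0.67, SE 0.05) and HSPB1 (0.53, SE 0.04) were higher. Of 27 glycolysis and hypoxia genes 20 rose and 2 fell, or 21 and 2 adjusted over the list alone (median 0.41, adjusted p 0.00281, and adjusted p = 0.605 with an estimated correlation), and 16 and 4 after rescaling. SLC2A3, a glucose transporter, rose from 19.2 ± 0.425 to 51.7 ± 1.59 TPM (SD, n = 3 each; 1.38, SE 0.05, limma adjusted p 5.01e-07), BNIP3L by 0.57 and PKM by 0.55. Of 20 p53 target genes 16 rose and 0 fell, as they did adjusted over the list alone (median 0.35, adjusted p 0.00325, and adjusted p = 0.456 with an estimated correlation), and 11 rose after rescaling. TP53INP1 (1.36), BTG2 (0.79), PMAIP1 (0.69) and the cell cycle inhibitor CDKN1A (0.51) rose. Of 30 G1 and S phase genes, 5 fell and 4 rose, as they did adjusted over the list alone (median -0.01, adjusted p 0.00961, and adjusted p = 0.715 with an estimated correlation). After rescaling 15 fell and 1 rose, with a median of -0.16. MCM7 (-0.47), UHRF1 (-0.40) and CDT1 (-0.27) fell and CCNE2 (0.55) rose.

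**Figure D4:**
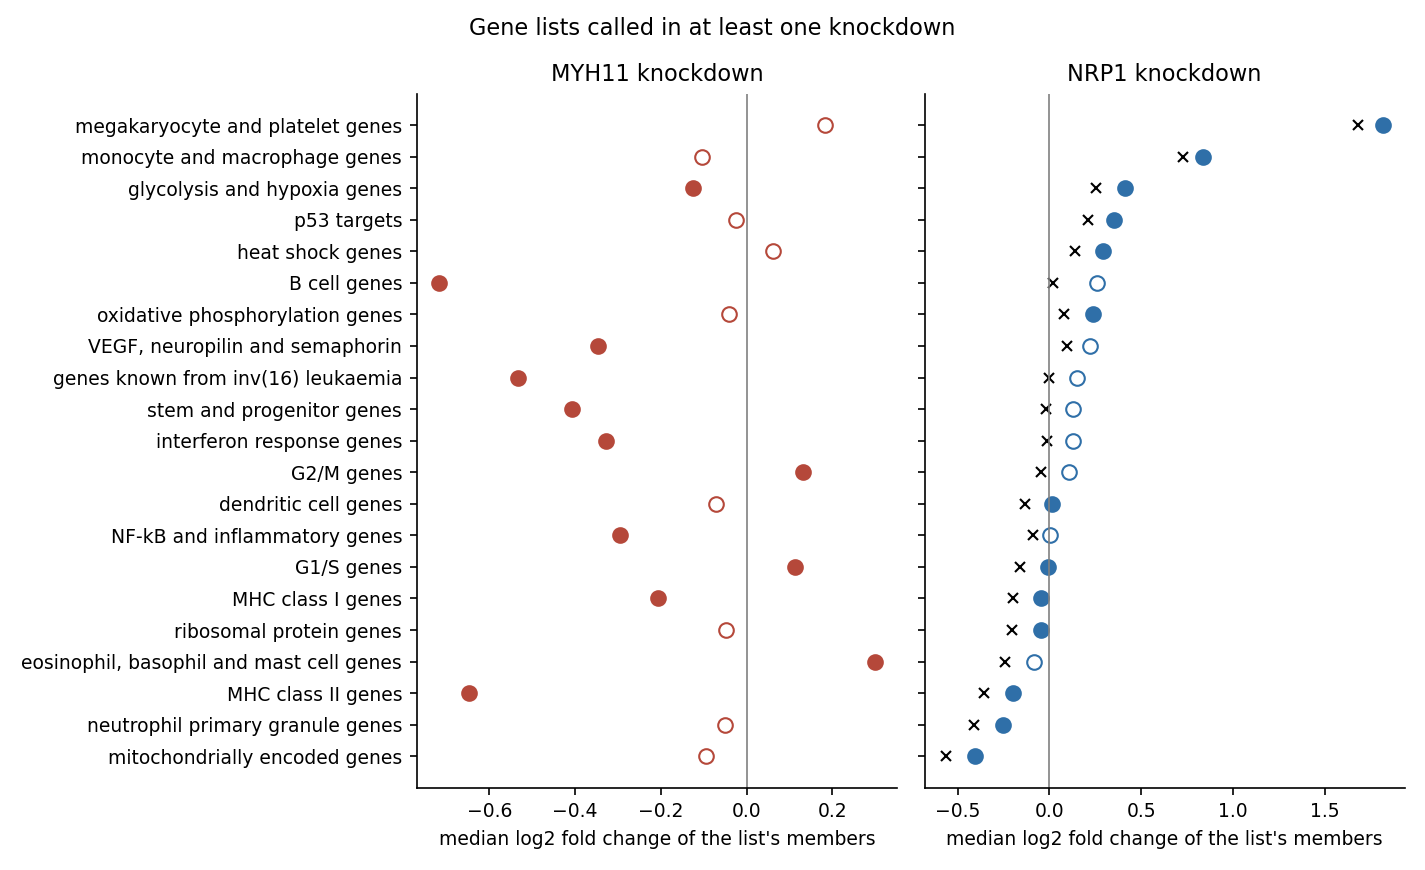
Points show the median log2 fold change of TPM + 1 over the tested members of each gene list called in either knockdown (n = 3 against 3), filled where camera called the list, with crosses for the NRP1 knockdown after median-of-ratios rescaling. Camera called 12 lists with MYH11 shRNA and 13 with NRP1 shRNA (0 and 0 with an estimated correlation), and rescaling ended the oxidative phosphorylation and primary granule calls of the latter and turned below 0 its dendritic cell (0.01 to -0.13), interferon, stem and progenitor, G2/M, inv(16) and NF-kB medians.

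Some genes changed in the same direction in both knockdowns. The embryonic myosin light chain gene MYL4 rose by 1.79 with MYH11 shRNA and 1.74 with NRP1 shRNA, ALDH1A1, which makes retinoic acid, by 1.37 and 1.78, and HPGD, which degrades prostaglandins, by 1.31 and 1.37. HBD, the delta globin gene, rose by 1.57 and 2.14, though it shares sequence with HBB. SNORA3B rose by 1.41 (SE 0.33) and 1.60 (SE 0.36). It had only 12 to 18 reads per library against 2 to 8 in set 1, and 2 to 9 against 1 in set 3. It also lies inside its host gene RPL27A, so its values are uncertain. Its call in set 1 was lost without MYH11 shRNA replicate 3 (1.249, adjusted p 0.0508) and with no filter on low values (adjusted p 0.0553). Genes lower in both were NRP1 itself, SERINC2 (-1.49 and -1.41), IGLL1 (-1.09 and -1.48), SAMD11 (-0.95 and -0.93) and EPX (-0.91 and -0.997).

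Of 12555 genes tested in both sets, 403 were higher in both where independent calls would give 298.4 (odds ratio 1.73, Fisher's exact p 2.9e-14, two-sided). A further 207 were lower in both, against 74.1 (odds ratio 3.94, Fisher's exact p 2.35e-46). After median-of-ratios rescaling 379 were higher in both against 242.0 and 536 lower against 314.2, and quantile normalization gave 372 against 232.5 and 548 against 325.6. With library weights 873 were higher in both against 850.6, and 504 lower against 345. Of the 1096 genes called in both, 610 (55.7%) moved the same way and 486 (44.3%) moved apart. The numbers that moved apart were near those of independent calls. Higher with MYH11 shRNA and lower with NRP1 shRNA were 62 against 55.0 (Fisher's exact p 0.312), and the reverse held for 424 against 402.1 (Fisher's exact p 0.164). Genes are not independent replicates, and across them the fold changes had a Pearson correlation of 0.0901 and a Spearman correlation of 0.0939.

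**Figure D5:**
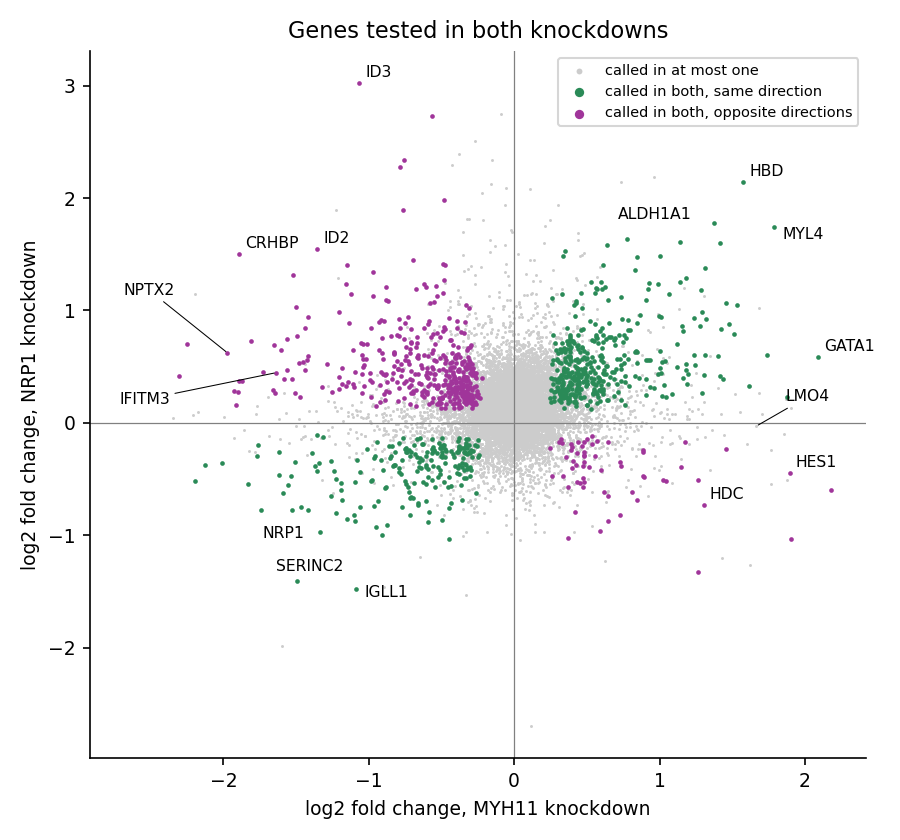
Each point is a gene tested in both sets, placed by its log2 fold change of TPM + 1 with MYH11 shRNA (horizontal) and NRP1 shRNA (vertical), with 3 libraries per group. The genes called in both include 403 higher in both, 207 lower in both and 486 that moved apart, and the correlation across genes was 0.0901.

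The knockdown effects were compared directly, as the fold change with MYH11 shRNA minus that with NRP1 shRNA over all 12 libraries. ID2, an inhibitor of differentiation, fell by 1.35 with MYH11 shRNA and rose by 1.55 with NRP1 shRNA, a difference of -2.90 (limma adjusted p 1.26e-10). The neuronal pentraxin gene NPTX2 fell by 1.97 and rose by 0.62 (-2.59), CRHBP fell by 1.90 and rose by 1.498 (-3.39), and the antiviral gene IFITM3 fell by 1.64 and rose by 0.45 (-2.08). In the opposite sense, HDC (2.03, adjusted p 1.32e-08), the LIM domain gene LMO4 (1.70), the transcription factor gene GATA1 (1.51) and SNX5 (1.36) responded more to MYH11 shRNA. SNX5, a sorting nexin, rose by 0.89 with MYH11 shRNA and fell by 0.47 with NRP1 shRNA. LMO4 was not called with NRP1 shRNA (-0.03, adjusted p 0.697) and was lower there after rescaling (-0.18, adjusted p 0.0182).

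The difference was called for 3888 of 13613 genes, with 676 above and 3212 below 0, and 94 and 485 of at least 2-fold. Its median of -0.14 carries the shift of set 3. Rescaling by median of ratios gave 1818 above and 2277 below, and quantile normalization 2047 and 2017. KDR differed by -1.53 (adjusted p 5.28e-05), MYC by 0.39 (0.00748) and MKI67 by 0.43 (0.0404), while NRP1, lowered in both, was not called as different (-0.36, adjusted p 0.0993). By camera 18 of 32 lists differed, and the list of eosinophil, basophil and mast cell genes alone held with an estimated correlation (adjusted p 6.08e-06, and 0.0232 so estimated). Megakaryocyte genes responded more to NRP1 shRNA (adjusted p 3.07e-05, and adjusted p = 0.251 with an estimated correlation), and MHC class II genes fell more with MYH11 shRNA (0.00276, and adjusted p = 0.414 with an estimated correlation). The 2 sets gave values that matched different transcript lengths for 8942 genes, so their levels were compared within sets and not across them.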

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

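Of the tests below, those of counting error and of the mitochondrial share for the megakaryocyte genes and both tests for the MHC class II genes were chosen after the results were seen. The test of counting error replaced one set beforehand whose criterion restated the rise, and it largely restates the rise too. Groups of 3 libraries are too small to test for outlying libraries. The results given first were called in opposite directions in the 2 knockdowns, and the difference itself was called by limma or, for lists, by camera. Differences are log2 fold changes with MYH11 shRNA minus those with NRP1 shRNA.

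The inhibitors of differentiation fell with MYH11 shRNA and rose with NRP1 shRNA. Their differences were -4.09 for ID3, -3.29 for ID1 and -2.90 for ID2. CRHBP (-3.39) and HOPX (-2.18) of the stem and progenitor list, SHD (-2.96), DUSP27 (-2.72) and NPTX2 (-2.59) moved in the same way. So did the collagen receptor GP6 (-3.10), the antiviral IFITM3 (-2.08), the small heat shock protein HSPB1 (-2.02), TNFAIP2 (-1.57), the chemokine CCL5 (-1.23) and the glycolytic enzyme PKM (-0.85). In the opposite sense, rising with MYH11 shRNA and falling with NRP1 shRNA, were the Notch target HES1 (2.34), the histamine enzyme HDC (2.03), RNF144A (1.40) and SNX5 (1.36). Adjusted p of these 18 differences reached at most 4.14e-06. G1 and S phase genes were called higher with MYH11 shRNA and lower with NRP1 shRNA (adjusted p of the difference 0.000277, and adjusted p = 0.528 with an estimated correlation). Glycolysis and hypoxia genes were lower and higher (3.07e-05, and adjusted p = 0.459 with an estimated correlation). The G1 and S phase calls rest on few genes, 1 higher and 1 lower of 30 with MYH11 shRNA and 4 and 5 with NRP1 shRNA (median -0.01). The first was lost in 3 of 6 fits without a library. Fry called that list in neither knockdown (adjusted p 0.391 and 0.682), nor the glycolysis list with MYH11 shRNA (0.259). The hairpins, the sets and the annotation behind the values differ together, and no further arm was analysed here to separate them.

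In the NRP1 knockdown more genes were higher than lower, 84.7% of the calls. Counting noise is argued against, because 85.4% of calls were higher among genes with at least 500 reads in every library of the set. Whether the smaller mitochondrial share of these libraries explains the excess of higher calls stays open. With mitochondrial genes left out, 63% of calls were higher, between the bounds of 60% and 75% set beforehand. The median log2 fold change of all genes tested was 0.14 with mitochondrial genes and 0.04 without them, so the share makes up part of the shift. A general rise of RNA, which TPM do not measure, was not tested.

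All 12 megakaryocyte genes rose with NRP1 shRNA. For 12 members the summed reads rose by more than counting error allows (exact binomial tests given the depths, adjusted over the list). All 12 had already been called higher from the same libraries, so this largely restates the rise and is not separate evidence. PPBP, with 8 reads in all scramble libraries, had 176 in the knockdown, a ratio of 10.9 to 51.5 (95% exact interval for counting error only). With mitochondrial genes left out the median of the list went from 1.82 to 1.78, and that of all genes from 0.14 to 0.04. The mitochondrial share thus makes up little of the rise. A shift of that size could not have undone the rise, so the outcome of this test was fixed beforehand. RNA of admixed platelets is argued against by the platelet chemokine gene PPBP, whose rise of 6.61 TPM was 0.0422 of the summed rise of ITGA2B and ITGB3; the table has no value for PF4, which the test was to include. A shift of the leukaemia cells towards megakaryocytes remains a hypothesis that may explain these values, and an unintended target of the hairpin was not tested.

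Of 12 MHC class II genes 12 fell with MYH11 shRNA, and 9 fell and 1 rose with NRP1 shRNA. The list was called lower in both, with adjusted p = 0.486 and 0.25 with an estimated correlation. CD74, on chromosome 5, was lower in 2 of 2 knockdowns (-0.69 and -0.53), so the fall was not confined to the HLA region. CD74 is a member of the list, and its fall was known when this test was chosen. It does not show whether reads were shared between the HLA genes, which stays open. Median-of-ratios rescaling gave list medians of -0.64 with MYH11 shRNA and -0.36 with NRP1 shRNA, the higher being -0.36. The median gene was 0.01 and 0.14 higher before it, so it could move the first little and only lower the second. This test therefore decides nothing about scaling. A common response of antigen presentation to both hairpins may underlie these falls, as a hypothesis, and a response to any active hairpin was not tested.

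For the comparisons within a set, 10 splits of the 6 libraries are too few for a share under 0.05. In set 1 the real split called 2081 genes and 12 lists, as 1 of 10 splits, and the highest other split called 0 genes and 7 lists. In set 3 the real split called 5335 genes and 13 lists, again 1 of 10, and the highest other called 0 and 5. For the difference, 2 of 100 drawn pairs of splits (of 200) called as many genes as the real 3888. The other of these pairs, with 4335 genes, keeps the real groups and exchanges knockdown and scramble in 1 set, so it sums the effects. For the shared calls the real pair alone, 1 of 100, gave as many as 610, and that same exchanged pair gave the highest other value, 486. Since other splits within a set called 0 genes, both outcomes follow largely from the calls of each set. They say nothing about the overlap of the calls, and chance is not excluded for the difference.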

How the results depend on the processing

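Leaving out mitochondrial genes, voom on recovered reads and leaving a hairpin's target out of its lists were chosen after the data were seen. Of the named genes called in the MYH11 knockdown, 44 to 46 of 46 kept their calls under each alternative that tested them all (other than a minimum fold), including each library left out, and in the NRP1 knockdown 47 to 50 of 50. With a mean of at least 5 TPM 44 of 44 and 48 of 48 that were tested did, and with mitochondrial genes left out 46 of 47 in the NRP1 knockdown.

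Scaling changed the balance of calls in the NRP1 knockdown most, from 84.7% higher to 51.8% and 47.9%. In the MYH11 knockdown that share was 43.6%, 43.7% and 45.6%. Over all alternatives it ranged from 33.6%, without MYH11 shRNA replicate 1, to 51.2%, with voom. Median-of-ratios rescaling gave 1381 genes higher and 1777 lower with MYH11 shRNA, 2420 and 2254 with NRP1 shRNA, 1818 above in the difference and 536 lower in both. Quantile normalization gave 1425 higher with MYH11 shRNA, 2249 higher and 2451 lower with NRP1 shRNA, 2047 above and 2017 below in the difference, and 920 shared, 548 of them lower. CBFB turned from 0.01 in the NRP1 knockdown to -0.15 and -0.17 under these, and PCNA from 0.03 to -0.12 with rescaling; they move because the median gene, 0.14 higher, is set to 0.

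With mitochondrial genes left out, NRP1 shRNA gave 2832 higher and 1663 lower, the difference 1424 above and the shared calls 344 lower. With voom, MYH11 shRNA gave 1838 higher, NRP1 shRNA 1644 lower, the difference 1424 above, and 1136 were shared (703 higher and 433 lower). Library weights gave 2355 higher and 3657 lower with MYH11 shRNA, 1235 lower with NRP1 shRNA, 6821 in the difference (1364 above and 5457 below) and 1377 shared (873 higher, where independent calls would give 850.6, and 504 lower); the cause was not tested for these. A fold of at least 2 by construction left 118 higher and 182 lower, 223 and 11, 579 differing (94 and 485) and 15 shared (13 and 2). With a mean of at least 5 TPM NRP1 was not tested, so 1 of 3 target calls remained.

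By estimated correlation 0 lists were called in the MYH11 knockdown and 0 in the NRP1 knockdown. Fry, which does not compare a list with other genes, called 11 lists in the MYH11 knockdown and 24 in the NRP1 knockdown. It did not call G2 and M phase (0.304), G1 and S phase (0.391) and glycolysis genes (0.259) in the first, nor G1 and S phase (0.682), ribosomal (0.28), MHC class I (0.341) and primary granule genes (0.0994) in the second, all called by camera. In the NRP1 knockdown it placed 4 lists that camera had as lower, uncalled, as higher: MYC and nucleolar targets (0.0457), late granulocyte (0.00244), B cell (0.00848) and NF-kB genes (0.0166).

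Leaving out each library gave 625 to 883 genes higher and 797 to 1328 lower in set 1, 3587 to 4288 and 551 to 864 in set 3, 3124 to 4364 differing and 439 to 594 shared, with 9 to 13 and 12 to 13 lists. The VEGF list also lost its call with no filter (0.083) and with library weights (0.171), and the inv(16) list with a mean of at least 5 TPM (0.091) and with weights (0.0929). Without MYH11 itself the inv(16) list was not called (0.0537), which left 11 of 12 lists, and without NRP1 13 of 13 in the NRP1 knockdown. In the NRP1 knockdown the granule and oxidative phosphorylation lists lost theirs under both scalings (0.162 and 0.317, 0.233 and 0.133), without mitochondrial genes (0.061 and 0.0868) and with voom (0.0629 and 0.0775). The monocyte list also lost its call without mitochondrial genes (0.0581), its median falling from 0.84 to 0.44 over 10 tested members in place of 8. The monocyte (0.397), dendritic (0.0562) and MHC class I lists (0.0562) lost theirs with no filter; the cause was not tested. Replicate numbers taken as a block gave 1289 higher and 1575 lower, and 4665 and 859. Correlations of same-numbered libraries were 0.0495 to 0.151, and those of differently numbered libraries -0.133 to 0.0716. A weak pairing by number therefore stays possible, and the main fits do not take it into account. Depth limits genes with few reads, such as NRP1 with 30 to 47 reads per MYH11 shRNA library.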

Other observations

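Of the hypothesis tests here, that of the whole response was chosen after the result was seen, and the genes named as examples were chosen after their values were seen.

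Transcription factor genes of blood cells changed in both knockdowns without a shared direction of their list. With MYH11 shRNA 6 of 20 rose and 3 fell (camera adjusted p 0.454), among them GFI1B (1.29), CEBPE (1.01) and TAL1 (0.61) against ERG (-1.22), GFI1 (-0.76) and FLI1 (-0.45). With NRP1 shRNA 10 rose and 3 fell (adjusted p 0.499), among them GFI1B (0.99), TAL1 (0.72), GATA2 (0.61) and GATA1 (0.58) against RUNX2 (-0.38). After rescaling 6 rose and 7 fell there (adjusted p 0.898). Of 5 erythroid genes with NRP1 shRNA, HBD (2.14), KLF1 (0.82) and HBB (0.78) rose (adjusted p 0.184). The list of endothelial, stromal and epithelial genes was not called there (adjusted p 0.403): 4 of 7 rose, TEK (2.27), CDH5 (1.78), TIE1 (1.04) and PECAM1 (0.45), and CLDN5 (-0.26) and KRT18 (-0.22) fell. The VEGF and semaphorin list was not called with NRP1 shRNA (4 of 12 higher, 1 lower, NRP1 itself, adjusted p 0.822), while KDR, SEMA3F (0.85) and PGF (0.44) rose.

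Adhesion genes moved in both directions. With MYH11 shRNA the tetraspanin CD9 (-1.14) fell and the integrin ITGB7 (0.88) and the chemokine receptor CXCR4 (0.59) rose, in all 6 higher and 5 lower of 20 (adjusted p 0.879; median 0.08, mean -0.07). With NRP1 shRNA CXCR4 (-0.96) fell and CD9 (0.89) and ITGB1 (0.65) rose, 9 higher and 8 lower (adjusted p 0.16). DDIT4, a stress-induced inhibitor of mTOR, rose in both (1.46 and 1.06), with 4 of 22 and 14 of 23 genes of the unfolded protein and ATF4 response higher (adjusted p 0.236 and 0.16). Cholesterol synthesis genes were called in 2 of 23 cases with MYH11 shRNA and 10 of 23 with NRP1 shRNA (adjusted p 0.582 and 0.403). With NRP1 shRNA 7 were higher and 6 lower after rescaling (adjusted p 0.611). DUSP6 (-0.84) and DUSP4 (-0.78), which damp ERK, fell with MYH11 shRNA and DUSP5 (1.07) rose with NRP1 shRNA, but the ERK list was not called (0.747 and 0.837). In the p53 list with MYH11 shRNA CDKN1A (-1.03) fell and TP53INP1 (0.83) rose (adjusted p 0.622).

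Other lists were not called. With MYH11 shRNA these were the endothelial, stromal and epithelial (adjusted p 0.199), mitochondrially encoded (0.222), apoptosis (0.387), MYC and nucleolar (0.526), dendritic (0.536), monocyte (0.536), oxidative phosphorylation (0.582), megakaryocyte (0.593), ribosomal (0.712), heat shock (0.781) and T and NK cell lists (0.879). With NRP1 shRNA they were the eosinophil, basophil and mast cell (0.0952), T and NK cell (0.162), inv(16) (0.413), NF-kB (0.419), late granulocyte (0.628), interferon (0.735), MYC and nucleolar (0.74), apoptosis (0.74), G2 and M phase (0.822), stem and progenitor (0.831) and B cell lists (0.959). In some of these lists camera, which compares with all other genes, differed in sign from the median or mean. With NRP1 shRNA, where the median of all genes was 0.14, the late granulocyte (median 0.37), B cell (0.26), inv(16) (0.15), G2 and M phase (0.11), adhesion (0.10), MYC and nucleolar (0.09) and NF-kB lists (0.01) were on camera's lower side. The eosinophil and T and NK cell lists were there with means above 0 (0.02 and 0.04). With MYH11 shRNA the heat shock and T and NK cell lists were on the higher side with means of -0.05 and -0.12, the transcription factor list with a median of -0.04, and the ERK list on the lower side with a median of 0.03.

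NRP1 was lower in both knockdowns, so its fall might carry the response to MYH11 shRNA. Of the genes called in both, 55.7% changed in the same direction, between the bounds of 50% and 60% set beforehand, which leaves this open for part of the response. The bounds take no account of the share that independent calls would give. Over the alternatives it ranged from 45.8% with library weights to 60% for changes of at least 2-fold. It was 59.4% and 59.1% under the scalings and 49.6% without MYH11 shRNA replicate 1, so both bounds were reached. In the main fits 44.3% of those genes were called in opposite directions with a called difference, a condition that removed none of the 486. Independent calls would give numbers near these (55.0 and 402.1, where 62 and 424 were found). So many opposite calls would go against its carrying all of the response. This cannot decide the question, since hairpins, sets and annotation differ together. NRP1 itself also fell to a different degree, 5.93-fold with MYH11 shRNA and 2.49-fold with NRP1 shRNA. Added NRP1 in cells with MYH11 shRNA was not analysed here.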
